A study of Drosophila melanogaster with 4 samples.

How the data were processed

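Testes of 2 genotypes were analysed, with 2 libraries each, and samples were grouped by the genotype in their labels. Per the labels' protocols, flies were kept at 23 °C, total RNA came from 50 testes per library, and 1 µg of it went into a TruSeq library sequenced on a MiSeq. Per the submitters' processing notes, TopHat and Cufflinks were used with genome build dm6; their versions, settings, gene annotation and use of strand are not given in the sources used here. The deposited values are FPKM per gene with the bounds of Cufflinks' 95% interval, also in FPKM, per the file headers. Every library held 16745 rows of 16510 gene names, and the 380 rows of 145 repeated names were summed. FPKM is scaled by the authors to the mapped fragments of each library and to transcript length, so that a change in a few abundant genes or in the length profile of a library moves the others.

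Read counts were not used. The number of fragments behind a value was estimated from its interval, as the square of 2 times FPKM over the distance to the upper bound, which assumes counting error alone. This was checked on rows with a single transcription start identifier and an estimate above zero and under 15 fragments. There 54.4% to 63.1% of the estimates lay within 0.05 of a whole number, where chance gives 10%. Rows with several start identifiers were not checked. The fragment numbers are therefore estimates, and no count model was run on them. Over all rows the estimates came to 1446647, 1468278, 3207719 and 3366747 per library.

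The test was limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3 on log2(FPKM + 1), for genes with a mean of at least 1 FPKM over the 4 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of low genes. An exact permutation test of 2 against 2 libraries cannot go below p = 0.33, two-sided. Gene lists fixed before the data were examined were tested with camera (preset correlation 0.01, and an estimated correlation) and fry (test of a movement in 1 direction), with adjustment over 19 lists of at least 3 tested members. Of the 21 lists, the mitochondrial genome list had no gene to test, and 2 Stellate genes were too few. None of the camera calls held with an estimated correlation, where the smallest adjusted p of all lists was 0.414. That test had low power with 4 libraries. The piRNA list had an estimated correlation of -0.017, below the preset 0.01, yet its unadjusted camera p went from 3.41e-05 to 0.0435. A call missed there does not by itself argue against a list, and the preset correlation remains an assumption. Chromosome groups were compared by two-sided Fisher's exact tests adjusted over 16 tests and by camera. The pericentromeric windows were set by hand on dm6, from 22 Mb on 2L and X, below 5.7 Mb on 2R, from 23 Mb on 3L and below 4.6 Mb on 3R.

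Gene identity, transcript length and exon overlap came from the Ensembl annotation of the same assembly. Current symbols, older symbols or synonyms matched 16262 names and 99.7% of the tested genes, and 97.7% of matched loci had the reference start. Transcript length was that of the longest annotated transcript, which need not be the one expressed in testes. Exon overlap was computed between the reference exons of matched names. Some of these gene models are longer than the loci in the files, and several names can match the same reference gene. A stated overlap therefore need not hold for the deposited values. Overlapping and antisense genes, and near-identical paralogs, are uncertain where fragments could be split between them. Genes named in the text followed a rule fixed together with the lists. Among called genes with at least 5 FPKM in the higher genotype and separate libraries, it took the 8 largest fold changes per direction and the next 5 with a name, then up to 4 genes with the smallest adjusted p per list or chromosome group, up to 4 genes per direction with the highest level among those listed at 0, and Su(var)3-9 with eIF-2gamma. Because that rule took mostly genes listed at 0, the largest changes among genes above 0 in all 4 libraries were added after the data were seen. Mst87F, Pkd2, SP, Hsp67Bb, CG34453, CG10513, CG10514 and the overlapping genes given with values or directions were also chosen after their values were seen.

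The procedure was tested on simulated data with 200 changed genes among 10784. In that simulation it recovered 23% of 2-fold and 73% of 4-fold changes, and 6.80% of its calls were not changed genes. The simulated values had normal noise and no depth difference, length trend or block of zeros between the groups. These shares therefore do not measure the error among the 2164 genes called in the data. The shifted simulated list was called with the preset correlation and missed with the estimated one. Alternatives changed the pseudocount, filter, scaling, variance model, replicate block, list correlation and windows, and left out each library in turn. Removal of a loess trend on transcript length (span 0.5), a fit on genes above 0 in all 4 libraries and the estimated list correlation under the other alternatives were added after the data were seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.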

Results

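Polyadenylated RNA of adult Drosophila melanogaster testes was sequenced in 4 libraries, 2 from flies labelled Su(var)3-9 mutant and 2 from wild-type flies. Each library was made from 50 testes dissected from males 3 days old, and the series describes the replicates of each genotype as biological. Su(var)3-9 is a histone methyltransferase that places methyl groups on lysine 9 of histone H3 in heterochromatin. The values were FPKM, fragment numbers scaled by the authors to transcript length and to the mapped fragments of the library. The fragments behind these values, estimated from the width of the deposited intervals, came to 1446647 and 1468278 in the libraries labelled mutant and to 3207719 and 3366747 in the wild-type libraries, so depth differed with genotype. At 4 to 6 FPKM the median half-width of the 95% interval was 51.3% and 52.1% of the value in the libraries labelled mutant, against 34.8% and 33.2% in the wild-type libraries.

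The targeted gene was read first. Su(var)3-9 (3R, 15259864 to 15263458, dm6) was listed at 0 FPKM in the library labelled mutant replicate 1 and at 7.83 FPKM in the library labelled mutant replicate 2, whose 95% interval ran from 4.84 to 10.8. The wild-type libraries held 7.93 and 9.74 FPKM. The difference between the genotypes was within the spread between the libraries labelled mutant (log2 fold change -1.72, SE 1.11, limma adjusted p = 0.339). The translation factor gene eIF-2gamma, which shares its first exons with Su(var)3-9, was at 57.7 and 50.6 FPKM in the libraries labelled mutant and at 51.6 and 46.5 FPKM in the wild type (log2 fold change 0.14, SE 0.11, limma adjusted p = 0.437). The shared part makes up 14.8% of the exon length of Su(var)3-9. The level of Su(var)3-9 did not set mutant replicate 2 apart from the wild type. Fragments could be split with eIF-2gamma over the shared 14.8% only. That would not by itself remove those of the unshared part, and mutant replicate 2, of similar depth, held an estimated 27.4 fragments of Su(var)3-9. The source of the listed 0 of mutant replicate 1 was not settled, and this 0 is not read as absence. The lesion of the mutant is not given in the sources used here, so this level cannot show whether the label of mutant replicate 2 is right. Every direction is given between libraries as labelled. Over 10784 genes, Pearson's r of log2 values across genes was 0.948 between the libraries labelled mutant, 0.943 between the wild-type libraries and 0.890 to 0.908 between a library of each kind, where genes are not independent replicates. Mutant replicate 2 was at 0.895 and 0.907 with wild type replicates 1 and 2, which argues against an exchange with a wild-type library. Depth split the libraries the same way, so the closeness of the libraries labelled mutant does not show the genotype of the flies.

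**Figure D1:**
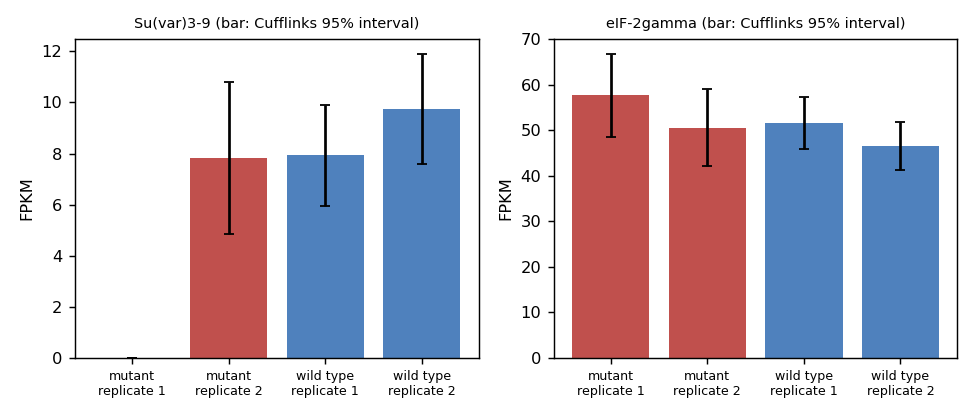
FPKM of Su(var)3-9 and of eIF-2gamma (vertical axes) in each of the 4 libraries, with the deposited 95% interval as error bars. Su(var)3-9 was listed at 0 in the library labelled mutant replicate 1 and at 7.83 FPKM in mutant replicate 2, beside 7.93 and 9.74 FPKM in the wild type.

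The series set testes of the mutant against wild-type testes. By camera with a preset correlation, gene lists for ribosomal proteins (median log2 fold change 0.55) and oxidative phosphorylation (0.38) were higher in the libraries labelled mutant, and the list for the piRNA pathway was lower (-0.44). The list for spermatid differentiation was higher as deposited (0.16) and turned to -0.10 under quantile normalization. None of these calls held with an estimated correlation, where the adjusted p was 0.626, 0.626, 0.414 and 0.414. The estimated correlation was above the preset 0.01 for the ribosomal protein and oxidative phosphorylation lists (0.42 and 0.22). It was below that for the piRNA and spermatid lists (-0.017 and -0.012). Their lost calls decide nothing, as that test has low power with 4 libraries. Of 10784 genes tested, 1229 were higher and 935 lower in the libraries labelled mutant (2164 in all, limma adjusted p under 0.05), and 806 of them differed by 2-fold or more, 368 higher and 438 lower. Of the 806, 195 were listed at 0 in both libraries of 1 genotype (65 higher, 130 lower), and among genes above 0 in all 4 libraries the balance turned, to 292 higher and 272 lower. Protein-coding genes made up 1943 of the 2164, and 211 were non-coding RNA genes. Quantile normalization gave 849 higher and 982 lower of all changed genes and 379 and 355 of those changed 2-fold, and a pseudocount of 5 gave 256 and 215 changed 2-fold, so the balance of directions rested on the processing. Leaving out 1 library left no gene past the threshold without either library labelled mutant, although 3852 and 3989 genes had an unadjusted limma p under 0.05, and left 182 genes without wild type replicate 1 (12 higher, 170 lower) and 262 without wild type replicate 2 (11 higher, 251 lower).

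**Figure D2:**
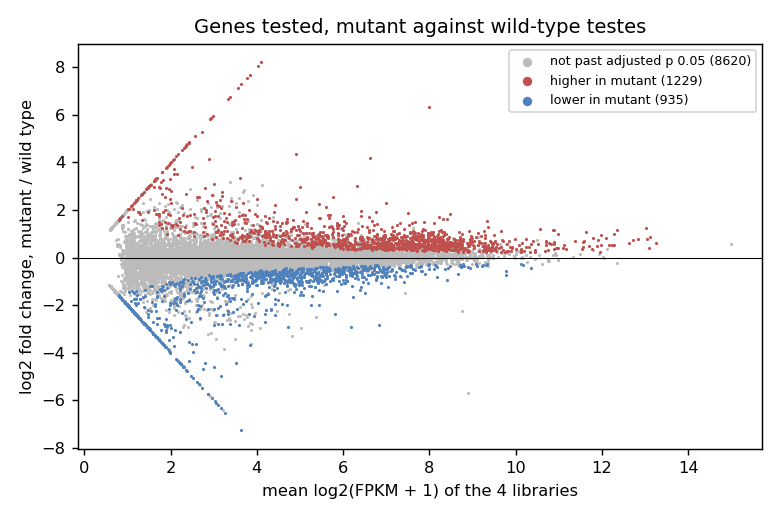
Log2 fold change between the libraries labelled mutant and the wild-type libraries (vertical axis, log2 of FPKM + 1) against the mean log2(FPKM + 1) of the 4 libraries (horizontal axis), 1 point per tested gene. The 1229 higher and 935 lower genes are coloured, and the straight outer lines are genes listed at 0 in both libraries of 1 genotype.

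Among called genes above 0 in all 4 libraries, scpr-B had the largest rise, from 27.5 ± 4.58 FPKM (SD, n = 2) in the wild type to 2261 ± 241 FPKM (SD, n = 2) in the libraries labelled mutant (log2 fold change 6.31, limma adjusted p = 0.00141). Its paralogs scpr-A and scpr-C can share its reads, so its level is uncertain. The other genes of this paragraph were chosen after their values were seen. CG8157 rose from 5.80 to 134 FPKM (log2 fold change 4.34), CG42828 from 22.8 to 416 FPKM (4.17) and CG34391, now DIP-delta, from 0.521 to 20.0 FPKM (3.81). Ude rose from 10.6 ± 1.29 to 89.1 ± 1.12 FPKM (SD, n = 2, log2 fold change 2.97), with 30.8% of its exon length overlapping Ets96B. That gene went the other way, from 6.81 and 6.42 FPKM in the wild-type libraries to a listed 0 in both libraries labelled mutant, so the level of Ude is uncertain. Adh, the alcohol dehydrogenase gene, rose from 22.7 and 15.3 FPKM in the wild-type libraries to 107 and 82.0 FPKM (log2 fold change 2.27), with 93.9% of its exon length overlapping Adhr. The transcription factor gene dimm rose by 2.46 on the log2 scale. The non-coding RNA gene CR41443 had the largest fall in this set, by 3.66 on the log2 scale. The homeobox gene inv fell from 12.9 ± 2.29 to 0.579 ± 0.221 FPKM (SD, n = 2, log2 fold change -3.14), the zinc finger gene rn from 9.44 to 0.392 FPKM (-2.92), the nuclear receptor gene Hr46 from 9.21 to 0.448 FPKM (-2.85) and the mesoderm regulator gene twi from 26.3 to 2.96 FPKM (-2.79). Hr46 and twi overlap CG12912 and CR42742 with 61.8% and 22.4% of their exon length. The synaptic scaffold gene Prosap fell from 21.4 to 2.25 FPKM (-2.79), and CG4480 fell from 304 to 42.7 FPKM (-2.82). The limma adjusted p of these genes lay between 0.00141 and 0.0156. The lower values of CG34391, inv, rn, Hr46 and CR41443 rested on an estimated 0.2 to 3.1 fragments per library and those of dimm, CG8157 and twi on 2 to 10, so the size of these changes is uncertain.

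Ribosomal protein and oxidative phosphorylation genes were read as lists. Of 87 ribosomal protein genes tested, 50 rose, none fell and 37 did not pass, and adjusted over the list alone 67 rose and 2 fell; their median log2 fold change was 0.55 (camera adjusted p = 1.65e-15). RpLP1 rose from 291 ± 5.10 to 501 ± 31.4 FPKM (SD, n = 2) and RpL39 from 1438 to 2825 FPKM. Of 90 oxidative phosphorylation genes, 29 rose, none fell and 61 did not pass, or 37 rose and 1 fell adjusted over the list alone (median log2 fold change 0.38, camera adjusted p = 3.48e-09). ATPsyn-Cf6, a subunit of ATP synthase, rose from 109 to 223 FPKM, and CoVa, a subunit of cytochrome c oxidase, from 230 to 372 FPKM. With an estimated correlation the adjusted p was 0.626 for both lists. By fry, which tests whether the genes of a list move one way and does not compare them with other genes, the adjusted p was 0.0823 for both. Fold changes also climbed with expression level, to a median of 0.33 in the highest of 10 classes of tested genes. The list tests did not compare genes of like level, so the shift of these lists was not separated from that trend.

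Genes of spermatid differentiation, of the piRNA pathway and of the early germline were followed next. Of 45 spermatid differentiation genes, 16 rose and 2 fell, or 20 and 3 adjusted over the list alone (median log2 fold change 0.16, camera adjusted p = 1.62e-04), and under quantile normalization the median turned to -0.10 (adjusted p = 0.382, range over the alternatives 2.61e-05 to 0.382). The male-specific transcripts Mst84Dc and Mst87F rose from 5417 ± 288 to 12916 ± 777 FPKM and from 6644 to 12021 FPKM, and ocn rose from 2994 to 4934 FPKM. Pkd2, a channel of the sperm tail, fell from 72.2 to 35.5 FPKM. None of 26 genes of the piRNA list rose and 4 fell, also adjusted over the list alone (median log2 fold change -0.44, camera adjusted p = 1.62e-04). These were tud (40.4 ± 0.365 to 14.2 ± 0.445 FPKM, SD, n = 2), qin (8.36 to 2.69 FPKM), armi (26.2 to 13.8 FPKM) and bgcn (38.7 to 26.9 FPKM). The piRNA and early germline lists share 2 genes, bgcn among them, so they are not separate evidence. With the length trend removed, qin (adjusted p = 0.0633) and bgcn (0.207) did not pass. Of 13 early germline genes, mei-P26 and bgcn fell and none rose, with 5 lower adjusted over the list alone (median log2 fold change -0.51, camera adjusted p = 0.00671). With the length trend removed no gene of that list passed, and mei-P26 moved from -0.89 to -0.04 (limma adjusted p = 0.842) and bgcn from -0.51 to -0.22. For mei-P26 that step used its longest annotated transcript, of 23041 bases, which need not be the one expressed in testes. With an estimated correlation the adjusted p was 0.414 for the spermatid and piRNA lists and 0.461 for the early germline list, and by fry it was 0.00703, 0.0257 and 0.0257. The meiotic arrest list held 1 gene that fell of 18, bol (705 to 568 FPKM, camera adjusted p of the list = 0.261), whose log2 fold change turned from -0.31 to 0.14 with the length trend removed (limma adjusted p = 0.203).

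Heterochromatin genes and the chromosomes rich in heterochromatin were examined because of the function of Su(var)3-9. Of 27 heterochromatin factor genes 1 rose and 2 fell, with the same counts adjusted over the list alone (median log2 fold change -0.33, camera adjusted p = 0.0258, and adjusted p = 0.461 with an estimated correlation). The list did not pass under quantile normalization (adjusted p = 0.110) or without wild type replicate 2 (adjusted p = 0.0893), in a range over the alternatives of 0.0176 to 0.506, and its fry adjusted p was 0.0316. HP1b rose from 8.14 ± 0.283 to 16.6 ± 1.19 FPKM (SD, n = 2), while the nuclear lamina genes Lam and LBR fell from 56.2 to 35.2 FPKM and from 11.5 to 4.95 FPKM. On chromosome 4, 17 of 70 genes fell and 5 rose (Fisher's exact test for the lower genes, odds ratio 3.42, adjusted p = 3.90e-04), and the median log2 fold change was -0.35 (camera adjusted p = 0.00331, and adjusted p = 0.610 with an estimated correlation). PlexB fell from 11.9 to 3.79 FPKM and 4E-T from 42.8 to 21.1 FPKM, and CG31997 rose from 1.65 to 14.3 FPKM, on an estimated 1.1 to 7.4 fragments per library. In the pericentromeric windows 29 of 233 genes fell and 21 rose (Fisher's exact test for the lower genes, adjusted p = 0.119). On the X chromosome 138 of 1620 genes rose and 85 fell, both below the shares elsewhere (Fisher's exact test, odds ratios 0.689 and 0.542, adjusted p = 3.90e-04 and 3.86e-07). Among 16 such tests, genes of 3R were also more often higher (327 of 2508, adjusted p = 0.0146) and genes of 2L more often lower (215 of 2142, adjusted p = 0.0412). Of all 10784 tested genes, 1229 were higher and 935 lower. By camera with the preset correlation, X, 3R and 2L did not pass (adjusted p = 0.871 for each). Their median log2 fold changes were 0.02, -0.01 and -0.04. Leaving out a library was a weak check of these 5 calls by Fisher's exact test, as no or few genes were then called to compare chromosomes. The calls did not all hold there. On the Y chromosome 1 of 18 genes rose and 4 fell (median log2 fold change -0.32, camera adjusted p = 0.117, and 0.0411 without mutant replicate 2 and 0.0246 on genes above 0 in all 4 libraries, range over the alternatives 0.0246 to 0.386; with an estimated correlation the adjusted p of these 2 was 0.670 and 0.399). Of 12 Y fertility genes, Pp1-Y1 rose, from 0.359 and 0 FPKM in the wild-type libraries to 13.3 and 15.8 FPKM (at most 1 estimated fragment per wild-type library), and kl-5, kl-2 and CG40948 fell, kl-5 from 16.7 and 20.2 FPKM to 4.93 and 5.07 FPKM (camera adjusted p of the list = 0.261). For kl-5 and CG40948 100% of the exon length of the matched reference gene overlaps that of CG41497 and CG42620. Names matched to the same reference gene would give this too, so an overlap of the listed loci was not shown. CG40948, now CCY, is listed at 3663953 to 3664555, but its reference transcript has 4002 bases. The levels of both genes are uncertain. With the length trend removed, kl-2 (limma adjusted p = 0.139) and CG40948 (0.05003) did not pass.

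**Figure D3:**
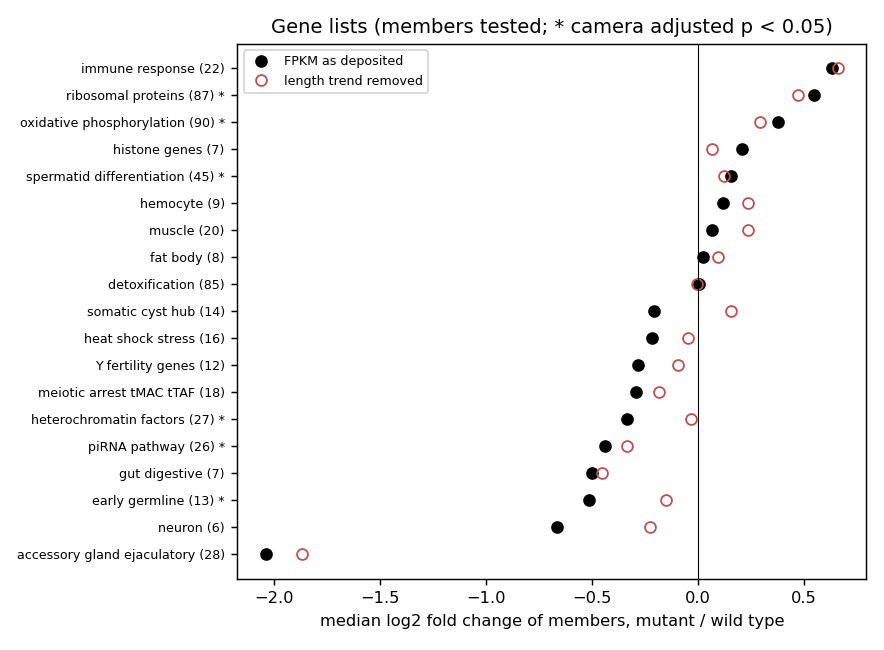
Median log2 fold change of the tested members of each gene list (horizontal axis), from FPKM as deposited (filled) and after a trend on transcript length was removed (open). The ribosomal protein list lay at 0.55 and 0.47 and the heterochromatin factor list at -0.33 and -0.03.

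Transcript length, taken from the longest annotated transcript of each gene, moved with these differences. The median log2 fold change was 0.26 in 2127 genes of 500 to 1000 bases and -0.46 in 1018 genes over 5000 bases, and Spearman's rho of fold change with length across genes was -0.316. After a loess trend on length was removed from each library, a step chosen after the data were seen, 1356 genes were called, 1236 of them called in the same direction before. The ribosomal protein, oxidative phosphorylation, spermatid and piRNA lists stayed past the threshold with the preset correlation (camera adjusted p = 6.80e-13, 3.66e-06, 0.0386 and 2.24e-04). With an estimated correlation none of them passed (adjusted p = 0.550, 0.670, 0.799 and 0.550). Fewer of their members were called after that step, 39 higher and 2 lower ribosomal protein genes, 16 higher oxidative phosphorylation genes, 9 higher and 2 lower spermatid genes and 2 lower piRNA genes. Over all alternatives with the preset correlation the highest adjusted p was 7.89e-07, 7.29e-04, 0.382 and 0.00459, and the lowest 2.22e-19, 1.86e-11, 2.61e-05 and 8.89e-05. The early germline list (median -0.51 before and -0.15 after, adjusted p = 0.318), the heterochromatin factor list (-0.33 and -0.03, 0.506) and chromosome 4 (-0.35 and -0.11, 0.237) no longer passed, as their medians moved towards 0. The accessory gland list, which had not passed before, passed with the preset correlation (adjusted p = 0.00838) and not with an estimated correlation (adjusted p = 0.799). Over all alternatives the adjusted p ran from 0.00548 to 0.318 for the early germline list and from 3.14e-04 to 0.237 for chromosome 4. The Fisher's exact tests of X (adjusted p = 0.0304 and 1.49e-07) and of 2L (0.0372) stayed past the threshold, and those of 3R (0.113) and of the lower genes of chromosome 4 (0.454) did not. By camera neither X nor 2L passed after that step (adjusted p = 0.598 and 0.648).

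**Figure D4:**
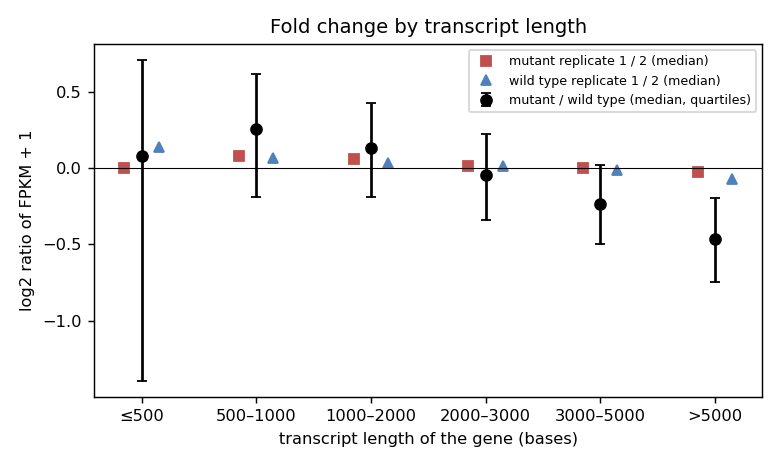
Median log2 ratio of FPKM + 1 (vertical axis) in classes of transcript length in bases (horizontal axis), with quartiles for the comparison of the genotypes, and medians for the replicates of each genotype against each other. The median between genotypes was 0.26 at 500 to 1000 bases and -0.46 over 5000 bases.

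Genes of other tissues were read as markers of what the dissected samples held. None of 28 accessory gland and ejaculatory genes passed the test, also adjusted over the list alone (median log2 fold change -2.04, camera adjusted p = 0.0502, and adjusted p = 0.835 with an estimated correlation). Their median was 33.3 FPKM in wild type replicate 1 and 0 FPKM in wild type replicate 2, beside 0 and 0.315 FPKM in the libraries labelled mutant. Some of the 28 passed the filter on mean FPKM through wild type replicate 1 alone, which raises the median of that library. SP, the sex peptide gene, was at 559 FPKM in wild type replicate 1, at 21.1 FPKM in mutant replicate 2 and at 0 in the other libraries. The list passed without wild type replicate 2 (camera adjusted p = 5.56e-11), with the length trend removed (0.00838), with a pseudocount of 5 (0.0401), without the filter (0.0407) and with the median ratio of each library set to 0 (0.0346), and over the alternatives its adjusted p ran from 5.56e-11 to 0.680. With an estimated correlation it passed under none of these 5 (adjusted p = 0.772, 0.799, 0.824, 0.801 and 0.811).

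**Figure D5:**
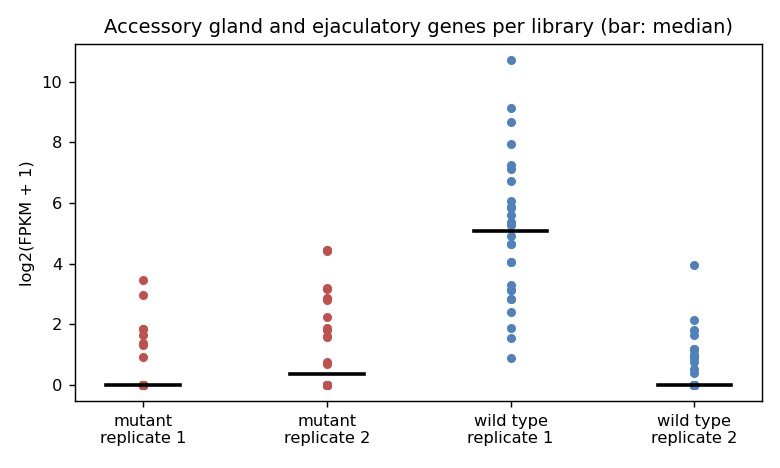
Log2(FPKM + 1) of 28 accessory gland and ejaculatory genes (vertical axis) in each library, 1 point per gene, with a bar at the median. The median was 33.3 FPKM in wild type replicate 1 and at most 0.315 FPKM in the other libraries.

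There were 637 genes with a mean of at least 1 FPKM in 1 genotype that were listed at 0 in both libraries of the other, 429 of them at 0 in the libraries labelled mutant and 208 in the wild type. Genes of general cell functions were among them, so a listed 0 is not read as absence, and no fold is given. The same 16745 rows, alike in name, locus and status, were listed in all 4 libraries, but whether both genotypes were processed with the same settings is not given in the sources used here, which limits the reading of these zeros and of the 195 calls among them. Of the 429, 138 were above 0 in wild type replicate 1 alone and 50 in wild type replicate 2 alone, and none of these was called. The 429 held 13 accessory gland and ejaculatory genes, 7 of them above 0 in wild type replicate 1 alone, and the 208 held none. Taf7, a subunit of a general transcription factor, was at 21.2 and 22.6 FPKM in the libraries labelled mutant, and Spase22-23, a signal peptidase subunit, at 111 and 104 FPKM, both listed at 0 in the wild type. Dbi was at 51.8 and 53.4 FPKM, jagn at 50.8 and 53.6 FPKM and Exo70, of the exocyst, at 15.6 and 14.2 FPKM in the wild type, all listed at 0 in the libraries labelled mutant. CG44435 (272 and 317 FPKM) and CG44044 (293 and 238 FPKM) were listed at 0 in the wild type, with 100% and 58.8% of their exon length overlapping CG44434 and Sulf1. CG43328, CG33191, CG42497, swif, mir-989, Ir75d, crim and cag were also at 17.9 FPKM or more in each library labelled mutant and listed at 0 in the wild type. In the reference, 100% of the exon length of CG43328, CG42497, swif and Ir75d overlaps another gene. The reference transcripts of CG44435, CG43328 and swif are longer than their listed loci (swif, 2074 bases against a locus of 8363374 to 8364388). Their overlap in the files is thus uncertain. The overlapping gene was called in the opposite direction for CG44435, CG33191 and cag, where CG44434, Pif1B and CG30020 fell, and for CG14384, CR31144, G6P and Atg12, named next, where grsm, RpL3, CG2964 and l(3)neo18 rose (limma adjusted p between 0.00508 and 0.0490), so their levels are uncertain. Oseg1, which overlaps Exo70, fell like it. CG14384 was at 152 FPKM in each wild-type library, and it, CR44674, CR45408, CR45636, CG6650, CR31144, G6P, Atg12 and snRNA:U2:14B were listed at 0 in the libraries labelled mutant and at 10.5 FPKM or more in each wild-type library. The highest values of all lay in single libraries, snoRNA:Or-CD8 at 7324 FPKM in wild type replicate 2, mir-995 at 3138 FPKM in wild type replicate 1, mir-4985 at 3467 FPKM in mutant replicate 2 and snoRNA:Or-CD1 at 3339 FPKM in mutant replicate 1, each listed at 0 in the other 3 libraries. These values rested on an estimated 2, 1, 1 and 1 fragments of transcripts of 92, 90, 101 and 106 bases, and mir-989 and snRNA:U2:14B on 1 to 3 fragments per library, so their levels are uncertain.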

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

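The length correction, the fit on genes above 0 in all 4 libraries and the estimated correlation under other alternatives were chosen after the data were seen. The count of 2164 genes stayed within 1.5 times under both pseudocounts, both filters, both scalings, robust eBayes and separation of the deposited intervals (1956 genes), and fell to 1103 (494 higher, 609 lower) with eBayes without trend and to 1356 with the length trend removed. The count of 806 genes changed 2-fold moved to 471 (256 higher, 215 lower) with a pseudocount of 5, where the larger pseudocount shrinks the folds of low genes. The 5 calls of chromosome groups moved to 3 with eBayes without trend and to 3 with the length trend removed, and the 6 lists past the threshold to 0 with an estimated correlation, as deposited and under each alternative fit, the left-out libraries and the replicate block included. The 637 genes listed at 0 moved to 224 where at least 5 FPKM was asked for. Leaving out 1 library, which leaves a lone library assumed to vary like the other genotype, gave 0 to 262 changed genes, 0 to 262 genes changed 2-fold, 0 to 2 chromosome group calls, 6 to 7 lists with the preset correlation and 0 with an estimated one, and log2 fold changes of Su(var)3-9 from -3.29 to -0.15. The spermatid list turned to -0.10 under quantile normalization, and bol and sls turned to 0.14 and 0.11 with the length trend removed. Apart from the alternatives' own construction, the cause was not tested. Su(var)3-9, at 0 in 1 library, had no value in the fit on genes above 0 in all 4 libraries. Of the values of named genes outside the left-out libraries, 1545 kept their side of the threshold, 37 lost it and 37 gained it with the same direction, and 2, those of bol and sls, lost it and turned. The replicate numbers were shared only as numbers (correlation across genes of the replicate differences -0.05), and with the replicate block 1671 genes were called, 1522 of them also called in the same direction without it, and 675 changed 2-fold, and the accessory gland list passed with the preset correlation (camera adjusted p = 0.00862) and not with an estimated correlation in the same fit (adjusted p = 0.869). Depth limited the libraries labelled mutant most, where values of 4 to 6 FPKM rested on medians of 15.2 and 14.7 fragments.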

Other observations

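Tests on overlapping genes, on zeros in parts of the gene set, on length within a genotype, on the late-spermatogenesis shift, on the accessory gland genes and on other splits were chosen after the result was seen; those on expected depth, on length within expression classes, on linkage and on neighbouring genes were written before their results were seen, the last after a cluster of higher genes had been noticed.

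Other gene groups held single movers. Of 85 detoxification genes 8 rose and 9 fell (camera adjusted p = 0.761), with GstE3 at 95.6 ± 8.87 FPKM in the libraries labelled mutant and 26.8 ± 0.859 in the wild type (SD, n = 2), and Cyp4ad1 at 2.01 and 20.7 FPKM, on an estimated 1.9 and 2.7 fragments in the libraries labelled mutant. Of 16 heat shock and stress genes 4 rose, Hsp27 (209 to 392 FPKM), Hsp23 (154 to 284 FPKM), Hsp67Bb, with 90.1% of its exon length overlapping Hsp22, and TotM, listed at 0 in the wild type and resting on an estimated 1.1 fragments in each library labelled mutant, so that its level is uncertain, and Hsp83 fell (680 to 543 FPKM; camera adjusted p = 0.761). Of 22 immune genes 2 rose, IM1, on 4 or 5 estimated fragments per library, and IM4 (camera adjusted p = 0.169, and 0.0317 without wild type replicate 1 and 0.0477 on genes above 0 in all 4 libraries, range over the alternatives 0.0317 to 0.459; with an estimated correlation the adjusted p of these 2 was 0.737 and 0.752), and of 6 neuronal genes nSyb rose and brp, Syx1A and Rdl fell, Rdl on at most 1.4 estimated fragments in a library labelled mutant (0.373, with a fry adjusted p of 0.00703, which does not compare the list with other genes). In the cyst and hub list of 14, hh rose and esg and ptc fell (0.761). In the muscle list of 20, Act87E rose and sls fell (0.713), but sls turned to a log2 fold change of 0.11 with the length trend removed (limma adjusted p = 0.600). Its correction used a longest annotated transcript of 56489 bases. Obp99a rose among 8 fat body genes (0.865), Amy-d fell among 7 digestive genes, on at most 1 estimated fragment in a library labelled mutant (0.271), His4r rose among 7 histone genes (0.761), and none of 9 hemocyte genes passed (0.696). With the length trend removed Hsp23, Hsp83, Syx1A, Rdl, hh and ptc did not pass either (limma adjusted p between 0.0519 and 0.139). The median, mean and test differed in sign for the heat shock (median -0.22, test upwards), fat body (0.02, test downwards), histone (mean below 0, test upwards) and detoxification lists (mean -0.07, test upwards). Of 2 Stellate genes neither passed, Ssl at means of 106 and 88.9 FPKM in the libraries labelled mutant and the wild type, and SteXh:CG42398 at 34.7, 0, 6.58 and 14.6 FPKM.

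Of 424 tested genes listed at 0 in 1 genotype, 46.0% overlapped the exons of another gene in the reference, against 30.5% of other tested genes (Fisher's exact test, p = 6.64e-11). The share was 71.7% for genes at 0 in the wild type and 32.6% for those at 0 in the libraries labelled mutant. These shares rest on reference gene models, some of them longer than the loci in the files. Fragments may have been assigned to the overlapping gene, mainly for genes at 0 in the wild type. That cannot hold for 7 protein-coding genes with no other gene at their locus and at least 5 FPKM in each library of the other genotype, Dbi and CG34453 among them. Lower depth may account for many zeros in the libraries labelled mutant, since no more than 30.8% of these genes had 10 or more fragments expected there, but it is argued against for 96 genes with 10 or more expected fragments and values above 0 in both wild-type libraries. Accessory gland tissue in wild type replicate 1 may account for part of the 429 genes at 0 in the libraries labelled mutant, since 13 of them were of its list, none of the 13 called. Genotype stays open as an explanation of the zeros, and so does processing that differed between the genotypes, which would follow the same split of the libraries; its settings and use of strand are not given in the sources used here.

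Shorter transcripts higher and longer ones lower in the libraries labelled mutant may partly reflect length-dependent differences between libraries, since Spearman's rho of length with wild type replicate 1 minus replicate 2 was -0.190 and with mutant replicate 1 minus replicate 2 was -0.105, both closer to 0 than the -0.316 between genotypes and the value for the mutant barely beyond the limit of 0.1 set for this test. Expression level in place of length is argued against, since the median rho within 10 classes of expression was -0.380. But the trend also went with expression, from a rho of 0.10 in the lowest class to -0.52 in the highest. The median log2 fold change itself climbed from -0.28 in the lowest class to 0.33 in the highest. A shift towards late-spermatogenesis transcripts cannot be told apart from the length trend, and the 2 genotypes differ in depth as well. The early germline list lost its call with the length correction (camera adjusted p = 0.318, median log2 fold change -0.51 before and -0.15 after). With the preset correlation the piRNA list (-0.44 and -0.34, camera adjusted p = 2.24e-04) and the spermatid list (0.16 and 0.13, 0.0386) kept theirs. Neither of these 2 passed with an estimated correlation (camera adjusted p = 0.550 and 0.799), and the spermatid median turned to -0.10 under quantile normalization.

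Accessory gland tissue is a candidate source of the signal in wild type replicate 1, where 85.7% of the 28 listed genes were highest, up to 1670 FPKM for Acp98AB and 559 FPKM for SP. In that library none of the 28 was listed at 0, against 20 and 14 in the libraries labelled mutant and 16 in wild type replicate 2. Est-6, Gld, Peb and Acp54A1 were not highest in it. The filter on mean FPKM kept 28 of 37 members, some of them through wild type replicate 1 alone. Acp98AB, Sfp96F and Sfp77F, for example, were at 0 in the other libraries. The share highest in that library and its lack of zeros are therefore partly set by the filter. Whether the mutant genotype also lowers these genes could not be decided. Wild type replicate 2 lay above both libraries labelled mutant in 21.4% of the 28 genes, but the 16 at 0 in it could not lie above. The listed genes summed to 3795 FPKM in wild type replicate 1 and 29.3 FPKM in wild type replicate 2. Genotype alone would not make the wild-type libraries differ in this way.

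A pair of hypotheses on position were tested on genes above 0 in all 4 libraries. A linked haplotype could have placed 2-fold changes near the mutated gene, but 6.33% of 821 genes within 5 Mb of Su(var)3-9 and 5.73% of other genes were changed (odds ratio 1.11, 95% interval 0.812 to 1.4985, Fisher's exact test, p = 0.481), and the upper bound lay only just under the limit of 1.5 set beforehand. Changed genes may lie next to each other more often than chance, as 30 neighbouring pairs changed 2-fold in the same direction, against a median of 15 in 10000 shuffles of the calls (permutation test, p = 2.00e-04, highest shuffle 32). A run of 3 higher genes was CG10513, CG10514 and CG11892 (3R, 25275790 to 25283237), the cluster noticed beforehand, which makes 2 of the 30 pairs, with CG10514 and CG11892 on at most 1 estimated fragment per wild-type library. Shared regulation, a linked variant and similar transcripts of related neighbours were not separated.

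The split by genotype called 2164 genes and the highest of the other splits called 0, with 93 genes at an unadjusted limma p under 0.05. With 4 libraries there are 3 splits and the real one was the largest (1 of 3), too few for a share under 0.05. Each other split sets 1 library of each genotype on both sides, so any difference between the genotypes widens its spread. Few calls there were thus likely whatever the cause, depth or processing included.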
